A study of Mus musculus with 21 samples.

How the data were processed

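Poly(A) RNA of 21 mouse libraries was sequenced, and the authors deposited 3 tables of values per gene. Per the labels, messenger RNA was taken with oligo(dT) beads and libraries were made with a NEBNext Ultra kit; the strand setting is not given. The labels list fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM with the mm10 build for every sample, and do not say which tool made which column. In the table of bone marrow eosinophils and granulocyte-monocyte progenitors (GMPs) and in the table of bone marrow-derived eosinophils (BMDEs) the deposited values are expected counts (estimated reads per gene, with fractions, not normalized). In the table of resting and cytokine-treated eosinophils the deposited values are read counts (whole numbers, not normalized). That table also holds a log2 column, which the authors made as the log2 ratio of their group means of FPKM, and p-values with an FDR, which the authors made with a test that is not named.

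Groups were taken from the sample titles before the data were examined, as were the tests, the gene lists, the rule for naming genes and the alternatives, except those said below to have been added later. The groups were bone marrow eosinophils (n = 3), GMPs (n = 3), resting eosinophils (n = 3), eosinophils treated with cytokines of type 2 immunity (T2, n = 3), control BMDEs (n = 2), BMDEs with deferoxamine (DFO, n = 3) and BMDEs with ferric ammonium citrate (FAC, n = 4). The T2 titles name a different interleukin for each replicate (IL-33, IL-34 and IL-35) beside IL-4 and GM-CSF, and the 3 libraries were kept as 1 group. The labels give the same protocol text, a BMDE culture, for every sample, so how the other cells were isolated is not known. Nothing in the labels says that replicates came from separate animals or cultures; p-values then measure only the spread between these libraries.

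Symbols were looked up by identifier, and the table's own symbol was used only where an identifier was not matched. The BMDE and eosinophil-GMP tables carry Entrez numbers and the T2 table Ensembl identifiers. Identifiers were matched to a symbol for 15899 of 15945, 16596 of 16645 and 22219 of 22274 genes in the GMP, BMDE and T2 tables. In the symbol columns 21, 23 and 1 symbols, in the same order, had been turned into dates and were not used. Coordinates, transcript length and GC content came from GENCODE M21 on GRCm38. Length and GC content were available for 96.9%, 97.2% and 99.9% of the genes tested in those tables.

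Total counts ranged from 25857382 to 28992668 per library in the GMP table, from 16073573 to 18995878 in the T2 table and from 16809789 to 17991878 in the BMDE table. Expected counts were rounded. Each table was fitted on its own in edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with genes kept by filterByExpr, TMM factors and the quasi-likelihood F test, which is two-sided. The 3 BMDE arms were 1 fit with a shared spread. Benjamini-Hochberg adjustment ran over the tested genes of each comparison. A gene was called at an adjusted p under 0.05, and the number changed at least 2-fold is given beside it. Tests covered 12214 genes for eosinophils against GMPs, 11345 for T2 against resting eosinophils and 12607 for the BMDE comparisons. Levels are counts scaled to library size with TMM factors (CPM), as mean ± SD, and log2 fold changes come from the fit with their standard error (SE). Fold changes against a group with 0 counts in every library are given as lower bounds against a floor of 3 counts over the group. The floors cover counting error only, whereas the SE comes from the quasi-likelihood F and includes the spread between libraries. The reads carry no molecular identifiers.

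Gene lists were fixed in advance, 34 in all. They cover iron uptake, iron storage and export, iron sensing and regulation, heme synthesis, iron-sulfur cluster assembly, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, the mitochondrial ribosome, glycolysis, the hypoxia response, fatty acid oxidation and lipid uptake, antioxidant and ferroptosis defence, and the integrated stress and unfolded protein response. Others cover eosinophil granule and surface genes, granulocyte transcription factors, progenitor markers, the cell cycle, ribosome biogenesis and Myc, IL-4 and STAT6 targets, GM-CSF and STAT5 targets, NF-kB and IL-33 targets, type 2 effector cytokines and chemokines, apoptosis regulators, immediate early genes and the interferon response. The rest are markers of neutrophils, monocytes and macrophages, mast cells and basophils, the erythroid lineage, B cells, T and NK cells, dendritic cells, and megakaryocytes and platelets. Of 757 genes in the lists, 23 are in 2 or more. Lists with at least 5 tested members were tested with camera, which compares a list with all other genes at a preset correlation of 0.01, adjusted over the lists of a comparison; 33 lists were tested in each. The mitochondrially encoded genes are absent from the GMP and BMDE tables, and 3 genes of the megakaryocyte and platelet list passed the filter in the T2 table. Camera with the correlation estimated per list and fry were run beside it. The fry test asks whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares a list with other genes.

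Genes are named by a fixed rule. A panel is given in every comparison: Tfrc, Fth1, Ftl1, Slc40a1, Hmox1, Epx, Prg2, Il5ra, Ccr3, Siglecf, Gata1, Mpo and Kit. Of each list, up to 3 called members with the smallest adjusted p may be named, or the member with the smallest p as a value where none was called. The 5 largest rises and 5 largest falls among called genes complete it, from genes whose groups do not overlap and whose mean level is above the median gene's, without predicted genes and immunoglobulin or T cell receptor segments. A few items were withheld for evaluation and are not reported.

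Signatures were the 200 genes a side with the smallest p, called and changed at least 2-fold, from the GMP and T2 tables. They were tested with camera in the 3 BMDE comparisons, adjusted over 6 tests each. The effects of DFO and FAC were compared across genes by Pearson correlation and covariance, beside 20 simulated sets of unchanged groups that shared the same controls, and by the overlap of calls beside the product of both counts over the genes tested.

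The code was tested on simulated data with 200 genes changed 1.5-, 2- or 4-fold at each table's own spread. At 2-fold it recovered 1.5% of changed genes for eosinophils against GMPs, 94% for T2 against resting, 77.6% for DFO, 89.6% for FAC and 85.1% for FAC against DFO. At 4-fold it recovered 34.8%, 98.5%, 95.5%, 97% and 98.5%. False calls were 2 of 26, 11 of 186, 5 of 133, 6 of 154 and 16 of 173. The changed genes were drawn at random, not by list, and camera called 1 of 33 lists for FAC against DFO and 0 in the others.

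Alternatives were RLE and upper-quartile factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a 2-fold minimum, leaving out each library in turn, the replicate number as a block, only the compared arms in the BMDE fit, fry, the estimated correlation, and signatures of 50 or 500 genes a side or without cell cycle and ribosome biogenesis genes. Offsets per library for transcript length and GC content (splines with 4 degrees of freedom, fitted to each library's deviation from the mean of all libraries of its table) were added after the data had been seen, as were correlations of the DFO and FAC effects with 1 control library for each arm. Leaving out 1 control library leaves 1, which is then assumed to vary like the other groups. Groups of 4 libraries were searched for values apart from the rest with Dixon's ratio. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.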

Results

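RNA sequencing of poly(A) RNA was deposited for 21 mouse libraries in 3 tables. The first table held 3 libraries of bone marrow eosinophils and 3 of granulocyte-monocyte progenitors (GMPs), the bone marrow cells from which granulocytes arise. The second held 3 libraries of resting eosinophils and 3 of eosinophils treated with cytokines of type 2 immunity (T2). The third held bone marrow-derived eosinophils (BMDEs), grown from bone marrow in culture, as 2 control libraries, 3 libraries with 5 µM deferoxamine (DFO), an iron chelator, and 4 libraries with 10 µM ferric ammonium citrate (FAC), an iron source. Per the labels BMDEs grew for 4 days in SCF and FLT3L at 100 ng/mL each and then in IL-5 at 10 ng/mL. DFO or FAC was added on day 4 and RNA was taken on day 7. The T2 titles name IL-4 and GM-CSF for all 3 libraries, with IL-33 for replicate 1, IL-34 for replicate 2 and IL-35 for replicate 3. The 3 were treated as 1 group, and which of these interleukins reached the cells cannot be read from the labels.

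Total counts per library were 25870192 to 28523399 in bone marrow eosinophils and 25857382 to 28992668 in GMPs. They were 16073573 to 18093548 in resting eosinophils and 17684961 to 18995878 in T2 eosinophils. In BMDEs they were 17080975 and 17181951 in controls, 16809789 to 17038127 with DFO and 17064745 to 17991878 with FAC. At these depths 3 counts over the 3 GMP libraries correspond to 0.0313 CPM. The most abundant gene was Mpo in the 3 GMP libraries (5.17% to 5.67% of counts) and in bone marrow eosinophil libraries 1 and 2 (4.59% and 2.85%), and S100a8 in eosinophil library 3 (5.19%). In every BMDE library it was Prg2.

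The panel genes given in every comparison lie, on GRCm38 (mm10), at these positions, with their Entrez numbers in brackets. Tfrc (transferrin receptor, 22042) spans chromosome 16 from 32608920 to 32632794. The ferritin genes Fth1 (14319) and Ftl1 (14325) span chromosome 19 from 9980598 to 9985098 and chromosome 7 from 45457944 to 45459884. Slc40a1 (ferroportin, the iron exporter, 53945) spans chromosome 1 from 45908068 to 45926523, and Hmox1 (heme oxygenase 1, 15368) chromosome 8 from 75093621 to 75100589. The eosinophil granule genes Epx (13861) and Prg2 (19074) span chromosome 11 from 87864000 to 87875536 and chromosome 2 from 84980461 to 84983632. The receptor genes Il5ra (16192), Ccr3 (12771) and Siglecf (233186) span chromosome 6 from 106710357 to 106749037, chromosome 9 from 124021972 to 124031689 and chromosome 7 from 43351341 to 43359531. Gata1 (14460) spans chromosome X from 7959260 to 7978071, Mpo (17523) chromosome 11 from 87793581 to 87804413, and Kit (16590) chromosome 5 from 75574916 to 75656722.

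The comparison of bone marrow eosinophils with GMPs asks which genes, those of iron handling included, differ between these 2 populations. Hmox1, Slc40a1, Fth1 and Ftl1, genes of heme breakdown, iron export and iron storage, were higher in the bone marrow eosinophil libraries. Hmox1 was at 256.7 ± 75.8 CPM (SD, n = 3) against 3.61 ± 0.596 CPM in GMPs, a log2 fold change of 6.15 (SE 0.316, adjusted p 0.000131). Slc40a1 was at 512.2 ± 179 CPM against 9.73 ± 0.886 CPM, a log2 fold change of 5.72 (SE 0.315, adjusted p 0.000148). Resting eosinophils of the second table, which was scaled on its own, had 7.975 to 8.385 CPM of Hmox1. Their Slc40a1 level was 90.25 to 97.84 CPM. The ferritin genes rose less, Fth1 by 1.16 (adjusted p 0.0149) and Ftl1 by 1.27 (adjusted p 0.00828) on the log2 scale. The call of Fth1 ended without any 1 of the GMP libraries and that of Ftl1 without GMP library 1, where the adjusted p reached 0.0858 and 0.0662. Tfrc did not differ beyond its spread (log2 fold change -0.08, adjusted p 0.825). Among iron uptake genes Slc11a1 rose by 5.33, Cd163 by 3.90 and Lcn2 by 8.01 on the log2 scale, and the libraries of the 2 groups did not overlap for any of these genes except Tfrc. In the same libraries neutrophil markers were higher (median 8.98 on the log2 scale). Monocyte and macrophage markers went both ways, with C1qa at 9.27 and F13a1 at -4.62. Whether the rises of iron genes belong to eosinophils or to other cells in these libraries was not tested. Of 10 tested genes of the iron storage and export list 4 were higher and 0 lower, or 5 and 1 adjusted over the list alone (camera adjusted p 0.000335; adjusted p 0.101 with an estimated correlation). Of 11 of iron uptake 4 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p 0.0147; adjusted p 0.15 with an estimated correlation).

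Genes of the eosinophil lineage were higher by large factors. Prg2 was at 16050 ± 7300 CPM against 84.8 ± 53.1 CPM in GMPs (log2 fold change 7.57, SE 0.703, adjusted p 0.001) and Epx at 3479 ± 1410 against 42.9 ± 21.2 CPM (6.34, SE 0.568, adjusted p 0.000871). Ccr3 rose by 10.24 and Il5ra by 6.55 on the log2 scale, Siglecf by 2.86, Alox15 by 8.46, Gata1 by 4.90 and Cebpe by 3.75. Of the eosinophil granule and surface list 20 of 22 genes were higher and 0 lower, the same numbers when adjusted over the list alone. Among granulocyte transcription factors 10 of 20 were higher and 1 lower, or 11 and 1 adjusted over the list alone. The progenitor genes Mpo and Kit differed by less than their spread allowed to call: Mpo was at 32200 ± 12900 CPM in eosinophils and 47090 ± 3670 CPM in GMPs (log2 fold change -0.55, adjusted p 0.267), and Kit at -0.67 (adjusted p 0.105). Cd34 fell by 1.76 on the log2 scale, and 4 of 18 progenitor markers were higher and 2 lower, or 4 and 4 adjusted over the list alone. The largest falls were Itga1 (-6.64), Il6st (-5.98), Met (-5.54), F13a1 (-4.62) and Irf8 (-3.65).

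Markers of other cell types were also higher in the bone marrow eosinophil libraries. Of the neutrophil list 13 of 14 genes were higher (median log2 fold change 8.98), with Ltf at 6059 ± 1360 CPM against 9.25 ± 2.02 CPM (log2 fold change 9.36, adjusted p 0.000113), Ngp at 10.70 and Cd177 at 6.88. The largest rises included Retnlg (12.40), Camp (11.82) and S100a9 (11.49). The neutrophil list took 3.43%, 6.66% and 13.7% of the counts of eosinophil libraries 1, 2 and 3, and 0.0417% to 0.0464% in GMPs; in resting eosinophils of the second table it took 0.276% to 0.299%. All 14 erythroid markers were higher (median 6.59), as were all 10 B cell markers (median 6.79, unchanged with genes at 0 in GMPs set to their bound) and all 8 mast cell and basophil markers (median 3.12). Every one of these 4 lists gave the same counts adjusted over the list alone. Ms4a1 and Fcmr had 0 counts in all GMP libraries and were at least 2680-fold and 1820-fold higher in eosinophils. Hba-a2 (6.75) and Hba-a1 (6.32) rose together; reads cannot always be assigned to 1 of these near-identical genes. Of 17 monocyte and macrophage markers 9 were higher, among them C1qa (9.27), and 6 lower, with the same counts adjusted over the list alone. Of 11 dendritic cell markers 5 were higher and 1 lower, or 6 and 2 adjusted over the list alone, with H2-Eb1 at 6.44. Of 5 T and NK cell markers 2 were higher, or 4 adjusted over the list alone, and of 9 megakaryocyte and platelet markers 3, the same adjusted over the list alone. Of the 74 members of the 6 lists from neutrophil to dendritic cell, 60 reached 10 CPM in bone marrow eosinophils and 26 in resting eosinophils.

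**Figure D1:**
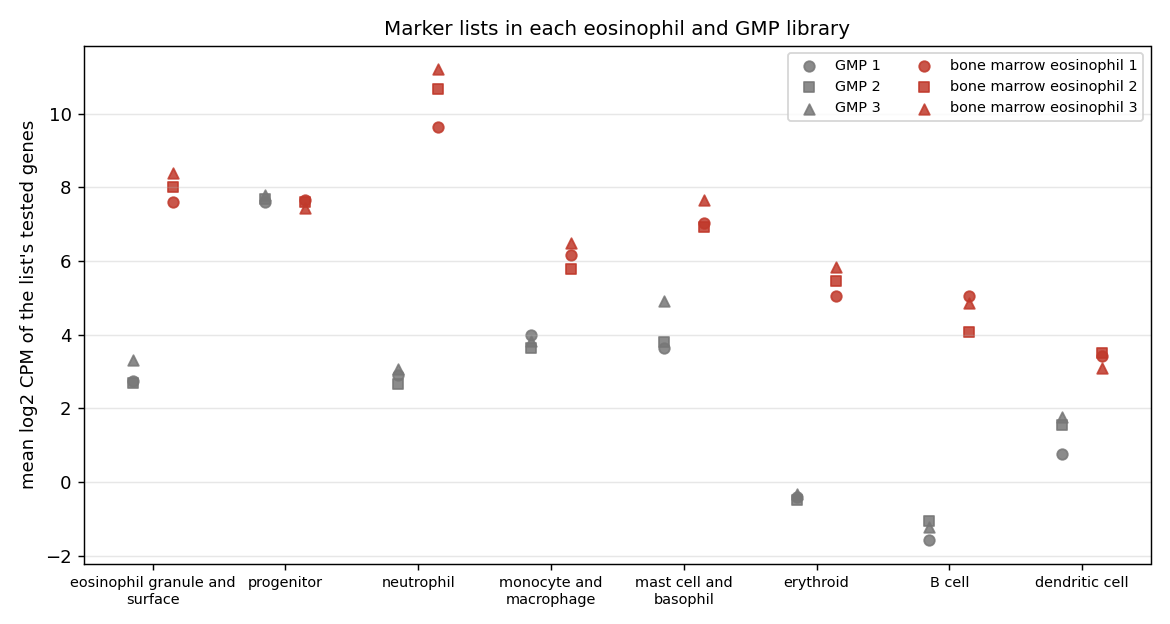
Mean log2 CPM of the tested genes of each marker list (vertical axis) for the 3 bone marrow eosinophil and 3 GMP libraries, 1 point per library. The neutrophil list lies between 9.63 and 11.2 in the eosinophil libraries and between 2.66 and 3.08 in GMPs, while the progenitor list lies between 7.43 and 7.8 in both groups.

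Of 12214 genes tested in edgeR, 2413 were called, 1585 higher and 828 lower in eosinophils, and 1789 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 4405. In 48.3% of the genes tested the 2 groups did not overlap, against 10% by chance. The number of calls moved with each library left out. It was 3013, 1452 and 4623 without eosinophil libraries 1, 2 and 3, and 747, 880 and 974 without GMP libraries 1, 2 and 3. Of these last calls, 747, 877 and 973 were also called with all libraries, none with the opposite sign. Leaving out any GMP library leaves fewer libraries to test, so these similar counts do not single 1 out. The lower calls moved most: there were 2545 higher and 2078 lower without eosinophil library 3 and 1022 and 430 without eosinophil library 2. Without GMP libraries 1, 2 and 3 there were 622 and 125, 704 and 176, and 754 and 220, and with length and GC offsets, added after the data had been seen, 1390 and 1121. Eosinophil library 3 stood apart from libraries 1 and 2. On the first principal component, with 68.2% of the variance, it lay at -182.08, libraries 1 and 2 at -34.02 and -43.35, and the GMPs between 76.69 and 94.29. Its TMM factor was 0.689, against 0.914 to 1.21 in the other 5 libraries.

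Camera at the preset correlation called 17 of 33 lists in eosinophils against GMPs, 15 higher and 2 lower. With an estimated correlation it called 0, and the 17 lists had adjusted p-values from 0.0531 to 0.794. The called lists named above had adjusted p-values of 1.93e-34 (neutrophil), 1.4e-31 (eosinophil), 1.93e-28 (erythroid), 8.81e-16 (B cell), 2.19e-06 (mast cell and basophil), 6.05e-05 (granulocyte transcription factors), 0.000335 (iron storage and export), 0.000717 (dendritic cell), 0.00526 (monocyte and macrophage) and 0.0147 (iron uptake). IL-4 and STAT6 targets were higher (median 1.82, 6 of 12 genes, 8 adjusted over the list alone, adjusted p 2.19e-06). Higher too were the interferon response (1.41, 8 of 20 genes, 11 adjusted over the list alone, adjusted p 0.000335), NF-kB and IL-33 targets (0.77, 4 of 21 genes, 9 adjusted over the list alone, adjusted p 0.0196) and glycolysis (0.27, 6 of 21 genes, 6 higher and 2 lower adjusted over the list alone, adjusted p 0.0203). Ribosome biogenesis and Myc genes were lower (median -0.70, 10 of 25 genes, 13 adjusted over the list alone, adjusted p 0.000245), and so were tricarboxylic acid cycle genes (-0.42, 3 of 19 genes, 3 adjusted over the list alone, adjusted p 0.046). Nuclear-encoded oxidative phosphorylation had a median of 1.06 and an adjusted p of 0.00234, with 2 of 76 genes called higher and 1 lower, 0 adjusted over the list alone; with offsets for transcript length and GC content its median was -0.11, and without eosinophil library 3 it was 0.41. Leaving out eosinophil library 3 ended the calls of oxidative phosphorylation (adjusted p 0.0946; 4.89e-07 to 0.794 over its alternatives), monocyte and macrophage markers (0.0502; 0.000664 to 0.317) and the tricarboxylic acid cycle (0.0502; 0.00292 to 0.43). The tricarboxylic acid cycle also lost its call without eosinophil library 1 (0.0682) and without GMP libraries 1 (0.069) and 3 (0.0653). NF-kB and IL-33 targets lost theirs without eosinophil library 1 (0.0682, over alternatives 0.00231 to 0.156), and glycolysis without GMP library 2 (0.0663, over alternatives 0.00852 to 0.415).

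Lists not called in eosinophils against GMPs were antioxidant and ferroptosis defence (7 of 20 genes higher, 9 adjusted over the list alone, adjusted p 0.0547), T and NK cell markers (0.0547), GM-CSF and STAT5 targets (0.101), the mitochondrial ribosome (0.108), apoptosis regulators (0.12), immediate early genes (0.181), type 2 effector cytokines and chemokines (0.312) and megakaryocyte and platelet markers (0.312). The other 8, with adjusted p-values from 0.607 to 1, were iron sensing and regulation, heme synthesis, iron-sulfur cluster assembly, the hypoxia response, fatty acid oxidation, the stress and unfolded protein response, progenitor markers and the cell cycle. Leaving out a library brought some of these past the threshold. The mitochondrial ribosome was called without eosinophil libraries 1 (0.003) or 2 (0.0456) or GMP library 3 (0.0414), over alternatives 0.003 to 0.843, with its median at -0.10 with length and GC offsets. Antioxidant defence was called without eosinophil library 1 (0.0284, over alternatives 0.00248 to 0.2) and immediate early genes without eosinophil library 2 (0.0452, up to 0.794 over alternatives). T and NK cell markers were called without eosinophil libraries 2 (0.0479) or 3 (0.0354) or GMP library 2 (0.0196), over alternatives 0.000188 to 0.206. The offsets also turned the medians of heme synthesis (0.12 to -0.16), iron-sulfur cluster assembly (0.26 to -0.12) and the stress response (0.11 to -0.29). Without eosinophil library 3 the medians of progenitor markers (-0.18 to 0.12) and megakaryocyte markers (0.72 to -0.60) turned. Median, mean and test differed in sign for iron-sulfur cluster assembly, fatty acid oxidation and the stress response. Across the 33 lists, adjustment over the list alone changed the counts of 21, by at most 5 genes.

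The comparison of T2 with resting eosinophils asks how cytokines of type 2 immunity change eosinophil genes, iron genes included. Fth1, Ftl1, Tfrc and Hmox1 rose with T2 cytokines, and Slc40a1 fell. Fth1 was at 10680 ± 276 CPM (SD, n = 3) against 826.6 ± 40.9 CPM at rest (log2 fold change 3.69, SE 0.045, adjusted p 2.17e-18) and Ftl1 at 6158 ± 568 against 2154 ± 28.8 CPM (1.52, SE 0.053). Tfrc was at 56.3 ± 5.95 against 12.3 ± 0.373 CPM (2.19, SE 0.085) and Hmox1 at 249.4 ± 23.9 against 8.18 ± 0.205 CPM (4.93, SE 0.084). Slc40a1 fell from 94.6 ± 3.93 to 45.5 ± 3.47 CPM (-1.06, SE 0.063, adjusted p 2.57e-10). Slc11a1 rose by 5.09 and Slc39a8 by 1.44 on the log2 scale, Alas1, the first enzyme of heme synthesis, by 3.84 and Fbxl5, a regulator of iron sensing, by 1.43; Fech (-1.52), Urod (-1.86) and Hfe (-1.48) fell. The libraries of the 2 groups did not overlap for any of these genes. Of 10 tested genes of iron uptake 6 were higher and 1 lower (camera adjusted p 0.00255; adjusted p 0.0948 with an estimated correlation), and of 10 of iron storage and export 7 and 2 (0.000658; adjusted p 0.193 with an estimated correlation). Of 7 of iron sensing and regulation 5 were higher and 2 lower, and of 16 of heme synthesis 3 and 9. Each of these counts was the same adjusted over the list alone.

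Eosinophil genes went both ways. Il5ra fell by 1.41 on the log2 scale, Ccr3 by 0.75, Epx by 0.71, Prg2 by 0.35 and Alox15 by 1.90, whereas Siglece rose by 4.31, Adgre1 by 1.66, Gata1 by 0.97 and Siglecf by 0.28. Kit rose by 0.51, and Mpo, at 0.729 ± 0.157 CPM with T2 cytokines and 0.95 ± 0.394 CPM at rest, was not called (-0.36, adjusted p 0.415). Of the eosinophil granule and surface list 10 of 20 genes were higher and 8 lower (median 0.08, and -0.04 with upper-quartile factors), the same adjusted over the list alone. Large rises were those of Cxcl2 (9.61), Ptgs2 (8.58), Il6 (8.43) and Ccl24 (8.42), and the largest falls Pbld1 (-7.15), Bckdha (-4.18), Mettl7a1 (-3.95), Nxpe4 (-3.94) and Fam102b (-3.67). Il13 rose from 1.51 ± 0.382 to 309.0 ± 20.1 CPM (log2 fold change 7.66, SE 0.102, adjusted p 5.08e-18). Among named genes the call of mt-Nd6 (-0.19, adjusted p 0.041) ended when a library was left out; the other 110 were called in every such fit.

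Of 11345 genes tested in edgeR 8632 were called, 4329 higher and 4303 lower, and 3122 changed at least 2-fold, 1326 higher and 1796 lower. At an unadjusted p under 0.05 there were 8796. The groups did not overlap in 77.7% of genes, against 10% by chance. Leaving out any 1 library left between 8300 and 8520 calls. Upper-quartile factors moved the median log2 fold change of all tested genes from -0.01 to -0.13, so changes smaller than that shift depend on the scaling. With those factors 3690 genes were called higher and 4927 lower.

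Camera called 14 of 33 lists in T2 against resting eosinophils, all higher, and with an estimated correlation 5: GM-CSF and STAT5 targets (adjusted p 0.0136), type 2 effectors (0.0165), IL-4 and STAT6 targets (0.0173), NF-kB and IL-33 targets (0.0173) and antioxidant and ferroptosis defence (0.0263). The other 9 had adjusted p-values from 0.0948 to 0.573 with an estimated correlation. NF-kB and IL-33 targets were higher in 23 of 25 genes and lower in 2 (median 2.64, preset adjusted p 3.42e-48). GM-CSF and STAT5 targets were higher in 14 of 15 and lower in 1 (2.35, 7.85e-23), IL-4 and STAT6 targets higher in 18 of 18 (3.45, 1.82e-19) and type 2 effectors in 10 of 10 (3.26, 3.69e-16). Antioxidant and ferroptosis defence was higher in 18 of 20 genes and lower in 2 (1.10, 2.96e-08), with Slc7a11 at 4.89 and Txnrd1 at 2.92. Glycolysis (17 of 21 genes higher and 2 lower, adjusted p 5.18e-07) and ribosome biogenesis and Myc (25 of 25, 8.88e-06) were called too. So were immediate early genes (10 of 16 higher and 3 lower, 11 and 3 adjusted over the list alone, 0.000434), iron storage and export (0.000658) and granulocyte transcription factors (14 of 20 higher and 5 lower, 0.00134). The remaining calls were the stress and unfolded protein response (16 of 21 higher and 3 lower, 0.00237), iron uptake (0.00255), apoptosis regulators (12 of 22 higher and 9 lower, 0.00387) and the hypoxia response (12 of 18 higher and 5 lower, 0.00757). Bcl2a1b (3.79) and Bcl2a1d (4.56), close paralogs that can share reads, were the apoptosis genes with the smallest p.

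The other 19 lists were not called in T2 against resting eosinophils. The adjusted p was 0.277 for the mitochondrial ribosome (44 of 78 genes higher and 8 lower, 44 and 7 adjusted over the list alone), 0.301 for eosinophil genes and 0.374 for iron-sulfur cluster assembly (16 of 27 higher, 5 lower). It was 0.513 for mast cell and basophil markers, 0.529 for oxidative phosphorylation (37 of 76 higher, 9 lower) and fatty acid oxidation, 0.574 for iron sensing and 0.643 for the tricarboxylic acid cycle (12 of 19 higher, 2 lower). It lay between 0.643 and 0.879 for heme synthesis, the cell cycle (4 of 35 higher, 10 lower), mitochondrially encoded genes (2 of 13 higher and 2 lower, 2 and 0 adjusted over the list alone) and the interferon response (6 of 20 higher, 12 lower). The same range held the markers of progenitors, neutrophils, monocytes and macrophages, erythroid cells, B cells, T and NK cells and dendritic cells. Median, mean and test differed in sign for fatty acid oxidation and for progenitor, neutrophil, mast cell and T and NK cell markers. Adjustment over the list alone changed the counts of 5 of the 33 lists, by at most 2 genes. In the columns the authors deposited, 7887 genes had an FDR under 0.05; 7691 of them were tested here and 7678 were called in both, 7427 with the same sign and 251 with the opposite one. The authors' log2 values, ratios of FPKM means, lay below those of edgeR by a median of -0.22.

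The comparisons within the BMDE table ask what removing or adding iron during eosinophil differentiation does to gene levels. Tfrc was lower with FAC, at 320.4 ± 13.2 CPM (SD, n = 4) against 484.8 ± 11.6 CPM in controls (n = 2; log2 fold change -0.60, SE 0.065, adjusted p 0.00178) and 480.7 ± 4.36 CPM with DFO (n = 3; FAC against DFO -0.59, SE 0.058, adjusted p 5.43e-05). With DFO it stayed at the control level (-0.01, SE 0.07, adjusted p 0.933). Slc40a1 was at 151.7 ± 3.48 CPM with DFO, 101.5 ± 1.95 CPM in controls and 85.8 ± 1.92 CPM with FAC; the change with DFO was 0.58 (adjusted p 0.00167), that with FAC -0.24 (adjusted p 0.0536), and that between FAC and DFO -0.82 (adjusted p 6.26e-06). Hmox1 rose by 0.56 with FAC (adjusted p 0.0485) and by 0.46 against DFO (adjusted p 0.0125). Ftl1 was higher with FAC than with DFO (0.72, adjusted p 0.00653) but missed the threshold against control (0.74, adjusted p 0.052). Every FAC library, at 5611 to 9608 CPM of Ftl1 with library 6 the highest, lay above the controls at 4079 and 4256 CPM. Fth1 was not called in any of the 3 comparisons (0.36, 0.39 and 0.02). Fth1 was nevertheless at 1680 ± 49.6 CPM with DFO and 1305 ± 37.4 CPM in controls, without overlap. The shared spread includes FAC library 6, at 2427 CPM, while FAC libraries 5, 7 and 8 were at 1555, 1322 and 1510 CPM. Cp, at 0.844 ± 0.188 CPM with FAC, was lower than in controls (-1.84, adjusted p 0.00338), Slc39a14 was lower by the log2 change of -0.73, and Lcn2 rose with DFO by 0.90, where neutrophil markers had a median of 0.73.

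**Figure D2:**
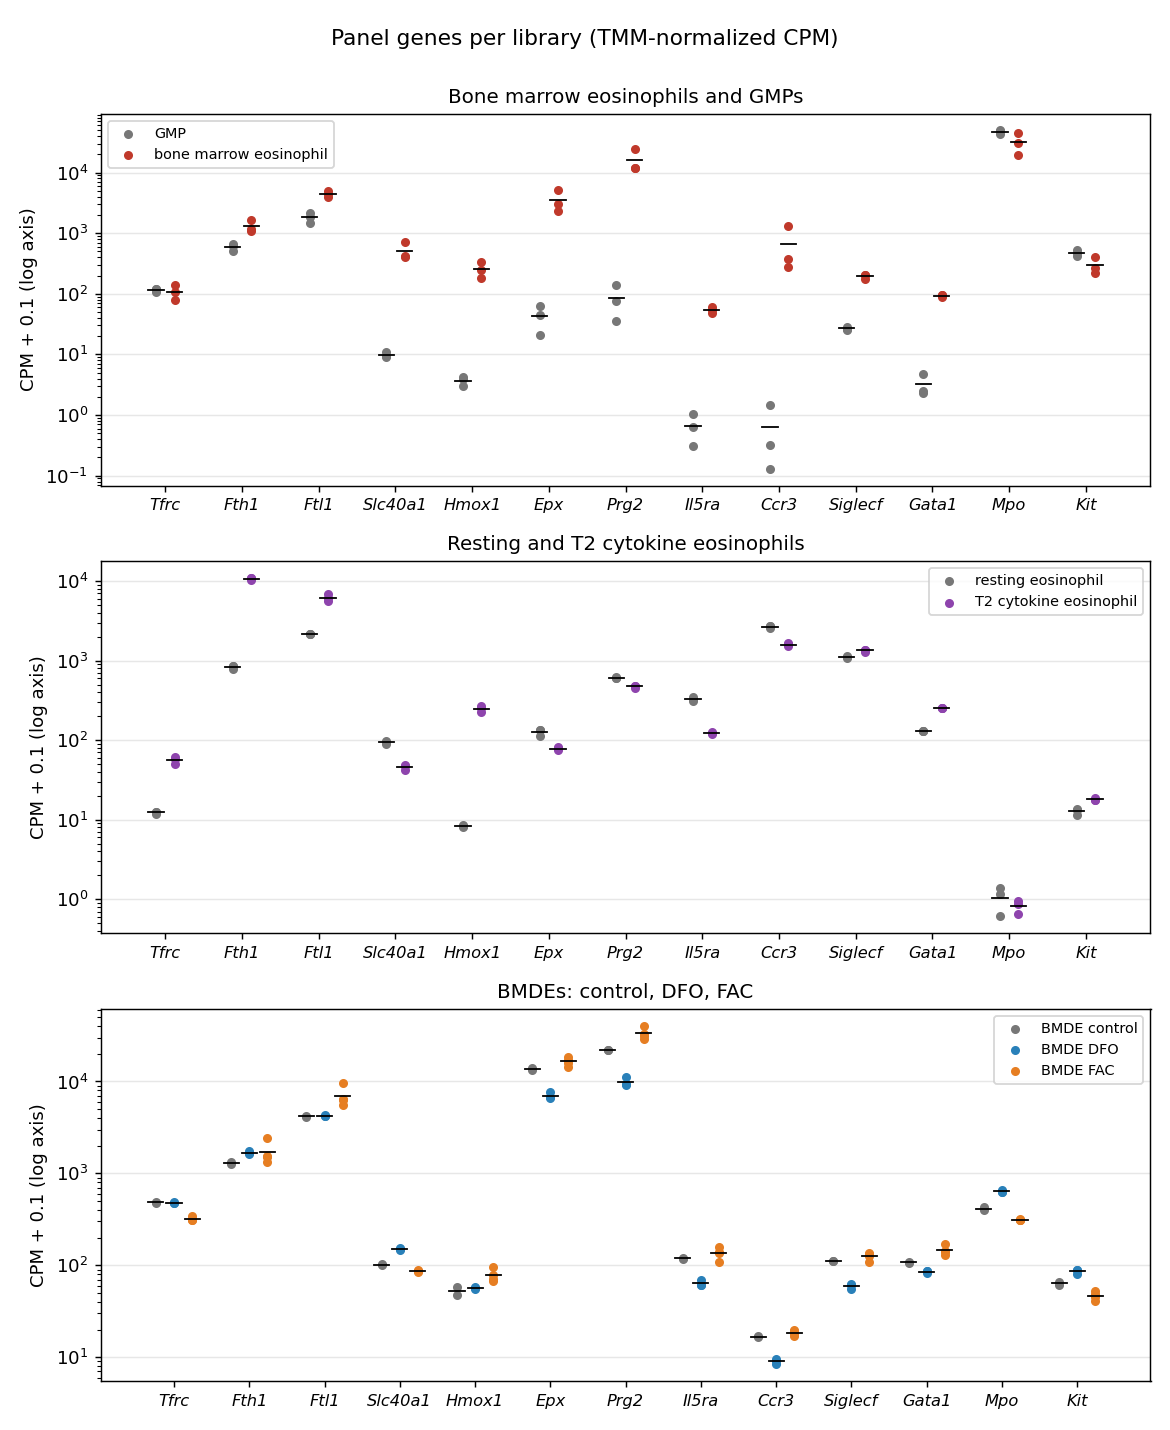
Level of each panel gene (CPM plus 0.1, log axis) in the libraries of the 3 tables; points are libraries and bars are group means. Tfrc lies near 480.7 CPM with DFO and 484.8 CPM in control BMDEs and at 320.4 CPM with FAC, and Fth1 at 826.6 CPM in resting and 10680 CPM in T2 eosinophils.

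Eosinophil genes as a list were lower with DFO (camera adjusted p 4.23e-19; adjusted p 0.00537 with an estimated correlation) and higher with FAC (2.07e-08; adjusted p 0.0176 with an estimated correlation). Prg2 fell from 21860 ± 79.6 CPM (n = 2) to 9927 ± 997 CPM (n = 3) with DFO (log2 fold change -1.14, SE 0.141, adjusted p 0.0021) and rose to 33460 ± 4870 CPM (n = 4) with FAC (0.61, SE 0.139, adjusted p 0.0347). Epx fell by 0.97 on the log2 scale with DFO, Il5ra by 0.91, Ccr3 by 0.90 and Siglecf by 0.90, each called; with FAC these 4 were not called (0.27, 0.17, 0.14 and 0.18), and between FAC and DFO they rose by 1.23, 1.08, 1.04 and 1.08. Gata1 was not called with DFO (-0.34, adjusted p 0.0825) and rose with FAC (0.44, adjusted p 0.0413). Alox15 changed by -1.13 and 0.67, Ear6 by -1.31 and 0.79 and Ear1 by -1.60 and 0.88 with DFO and FAC; Ear1, Ear2 and Ear6 are close paralogs that can share reads. Mpo rose with DFO (0.64, adjusted p 0.00154) and fell by 0.40 on the log2 scale with FAC (adjusted p 0.00999), and Kit changed by 0.44 and -0.44. Of 22 eosinophil granule and surface genes 12 were lower and 0 higher with DFO, or 14 and 1 adjusted over the list alone, and 6 were higher and 0 lower with FAC, or 9 and 1 adjusted over the list alone.

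Named markers of dendritic cells, neutrophils and monocytes moved against the eosinophil genes. Siglech was at 250.8 ± 9.93 CPM with DFO, 118.6 ± 7.84 CPM in controls and 49.5 ± 3.89 CPM with FAC (log2 fold changes 1.08 and -1.26). Ltf changed by 1.07 and -0.81 with DFO and FAC, Flt3 by 1.05 and -0.77, Ccr9 by 1.20 and -1.45, Lyz2 by 0.64 and -0.59 and Irf8 by 0.91 and -0.79. Ifit2, a gene induced by interferon, changed by 1.06 and -1.13. B cell markers were lower in both arms, with Ms4a1 at -1.11 with DFO and -0.90 with FAC. Both arms are compared with the same 2 controls, and error in these moves both effects alike: simulated unchanged groups gave a correlation of 0.634 across genes. Between FAC and DFO B cell markers were not called (adjusted p 0.692, median -0.20). Cell cycle genes fell with DFO, with Rrm2 at -0.60, while Ccnd1 rose by 1.05 with DFO and fell by 1.08 on the log2 scale with FAC. With FAC against DFO the largest rises were Selenom (2.74), Inpp5j (2.54), Naaladl1 (2.50), Ear1 (2.48) and Ear2 (2.28), and the largest falls Ccr9 (-2.65), Siglech (-2.34), Rnf213 (-2.15), Ccnd1 (-2.14) and Kmo (-2.12).

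With DFO against control 1460 of 12607 genes were called in edgeR, 814 higher and 646 lower, 195 of them at least 2-fold and 3280 at an unadjusted p under 0.05. With FAC against control 761 were called, 222 higher and 539 lower, 142 at least 2-fold and 2836 at an unadjusted p under 0.05. Between FAC and DFO 6080 were called, 2959 higher and 3121 lower with FAC, 1262 at least 2-fold and 7052 at an unadjusted p under 0.05. The first principal component, with 64.2% of the variance, placed the DFO libraries between -39.74 and -35.83, the controls at -5.03 and -4.79 and the FAC libraries between 17.98 and 52.71, with FAC library 6 at the upper end.

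The counts against control fell without any 1 library other than FAC libraries 6 and 7, and rose without either of these. Without FAC library 7 there were 1642 calls with DFO and 1066 with FAC. No gene called both in such a fit and with all libraries had the opposite sign. With DFO there were 320 and 217 calls without control libraries 1 and 2, 592, 624 and 699 without DFO libraries 11, 12 and 9, and 4899 without FAC library 6, which enters through the shared spread. With FAC there were 76 and 163 without control libraries 1 and 2, 345, 2728 and 335 without FAC libraries 5, 6 and 8, and 396, 410 and 417 without DFO libraries 11, 12 and 9. Between FAC and DFO the count stayed between 4250 and 7855. The direction that held the majority of calls turned in some fits. Without FAC library 6 there were 2368 higher and 2531 lower with DFO, 1254 and 1474 with FAC, and 4003 and 3852 between FAC and DFO. With length and GC offsets, added after the data had been seen, there were 1320 higher and 1595 lower with DFO, 927 and 751 with FAC, and 4261 and 2772 between FAC and DFO. FAC library 6 differed from the other FAC libraries by transcript length: across 12257 genes the Spearman correlation of its deviation from their mean with length was -0.658, and its median deviation was 0.463 in the fifth of genes with the shortest transcripts and -0.475 in the fifth with the longest. In FAC libraries 5, 7 and 8 that correlation was 0.37, 0.615 and 0.402, which library 6 raises, since it is among the 3 that each is compared with. In the DFO libraries it lay between -0.162 and 0.093. Against the mean of all BMDE libraries, length and GC content accounted for 37.7% of the deviation of FAC library 6 and for 4.8%, 2.7% and 4.4% in FAC libraries 5, 7 and 8; genes are not independent replicates.

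Many of these calls against control ended in fits that left out 1 library. Several ended in most such fits, so no single library accounts for them. Of 84 named genes called with DFO 29 were called in every fit that left out 1 library, of 65 with FAC 16, and of 110 between FAC and DFO 109, all but Ncr1. With DFO, Il5ra lost its call without control library 2 (adjusted p 0.051) and Kit in 6 of 9 such fits (highest adjusted p 0.227). With FAC, Hmox1, Prg2, Gata1 and Kit lost theirs in 7 of 9 fits (highest adjusted p 0.38, 0.252, 0.278 and 0.279) and Mpo without either control library (0.167), while that of Tfrc held in all 9.

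Camera called 19 of 33 lists with DFO against control. Higher were dendritic cell markers (median 0.75, 7 of 12 genes, 9 adjusted over the list alone, adjusted p 1.78e-13), the interferon response (0.74, 9 of 20, 14 adjusted over the list alone, 2.76e-10), neutrophil markers (0.73, 9 of 15, 11 adjusted over the list alone, 8.39e-09), and NF-kB and IL-33 targets (0.29, 9 of 25, 12 adjusted over the list alone, 5.92e-05). Megakaryocyte and platelet markers (0.46, 3 of 10, 6 adjusted over the list alone, 0.000174), progenitor markers (0.38, 7 of 18 higher and 2 lower, 8 and 2 adjusted over the list alone, 0.00308) and monocyte and macrophage markers (0.29, 4 of 17 higher and 2 lower, 7 and 2 adjusted over the list alone, 0.0116) were higher too. Lower were eosinophil genes (median -0.70, adjusted p 4.23e-19), the cell cycle (-0.38, 21 of 35, 26 adjusted over the list alone, 2.33e-11), the stress and unfolded protein response (-0.30, 9 of 22, 12 adjusted over the list alone, 1.09e-06), and ribosome biogenesis and Myc (-0.26, 2 of 25, 5 adjusted over the list alone, 2.3e-05). So were B cell markers (-0.63, 4 of 8, 5 adjusted over the list alone, 2.52e-05), glycolysis (-0.40, 10 of 21 lower and 1 higher, 12 and 1 adjusted over the list alone, 2.88e-05) and the mitochondrial ribosome (-0.23, 3 of 78, 0 adjusted over the list alone, 5.92e-05). The remaining lower lists were oxidative phosphorylation (-0.19, 0 of 76, 0.00188), the tricarboxylic acid cycle (-0.17, 1 of 19, 0.00479), the hypoxia response (-0.25, 3 of 21, 5 adjusted over the list alone, 0.00908), heme synthesis (-0.11, 3 of 15, 0.0144) and GM-CSF and STAT5 targets (-0.10, 5 of 16 lower and 2 higher, 0.0232). With an estimated correlation 5 of the 19 calls held: eosinophil genes (adjusted p 0.00537), the cell cycle (0.0156), dendritic cell markers (0.0156), B cell markers (0.028) and ribosome biogenesis (0.0482). The other 14 had adjusted p-values from 0.0725 to 0.721 with an estimated correlation. GM-CSF and STAT5 targets lost the call without control library 1 (0.0799, over alternatives 0.00365 to 0.157) and monocyte and macrophage markers without control library 2 (0.0995, over alternatives 0.0017 to 0.379).

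Camera called 18 of 33 lists with FAC against control. Higher were the stress and unfolded protein response (median 0.36, 9 of 22 genes, 12 adjusted over the list alone, adjusted p 1.19e-10), oxidative phosphorylation (0.34, 0 of 76 genes called, 1.63e-08), eosinophil genes (0.24, 2.07e-08), and antioxidant and ferroptosis defence (0.36, 6 of 20, 7 adjusted over the list alone, 8.42e-07). Higher too were the mitochondrial ribosome (0.22, 0 of 78, 1.25e-05), glycolysis (0.24, 0 of 21, 8 adjusted over the list alone, 0.000102) and the cell cycle (0.15, 4 of 35 higher and 1 lower, 9 and 2 adjusted over the list alone, 0.00101). The others were type 2 effectors (0.77, 2 of 9, 0.0128), iron-sulfur cluster assembly (0.16, 0 of 28, 0.0249), GM-CSF and STAT5 targets (0.24, 3 of 16 higher and 1 lower, 5 and 2 adjusted over the list alone, 0.0249) and fatty acid oxidation (0.14, 1 of 16, 0.0338). Lower were dendritic cell markers (median -0.78, 6 of 12, 1.67e-14), the interferon response (-0.78, 9 of 20, 16 adjusted over the list alone, 2.1e-13), and B cell markers (-0.63, 4 of 8, 5 adjusted over the list alone, 8.59e-09). Lower too were neutrophil markers (-0.38, 5 of 15, 8 lower and 1 higher adjusted over the list alone, 1.25e-05), monocyte and macrophage markers (-0.21, 6 of 17 lower and 1 higher, 7 and 2 adjusted over the list alone, 0.00256), megakaryocyte and platelet markers (-0.31, 2 of 10, 5 adjusted over the list alone, 0.00908) and progenitor markers (-0.22, 4 of 18 lower and 1 higher, 5 and 2 adjusted over the list alone, 0.0177). With an estimated correlation 4 held, antioxidant and ferroptosis defence, B cell and dendritic cell markers (0.0139 each) and eosinophil genes (0.0176), and the other 14 had adjusted p-values from 0.144 to 0.583. Without FAC library 6 the calls of iron-sulfur cluster assembly (0.273, over alternatives 0.00831 to 0.583), fatty acid oxidation (0.121, over alternatives 0.0184 to 0.452) and type 2 effectors (0.0835, over alternatives 0.00694 to 0.416) ended. Fatty acid oxidation also lost its call without control library 1 (0.0614). FAC library 6 also set much of the size of several shifts. Without it the median was 0.15 instead of 0.34 for oxidative phosphorylation and 0.08 instead of 0.22 for the mitochondrial ribosome. It was 0.06 for iron-sulfur cluster assembly, 0.07 for fatty acid oxidation, 0.48 for type 2 effectors, 0.23 for antioxidant defence, 0.16 for GM-CSF and STAT5 targets and -0.46 for monocyte and macrophage markers. The mean log2 CPM of oxidative phosphorylation genes was 6.93 in FAC library 6, 6.37, 6.17 and 6.31 in FAC libraries 5, 7 and 8, and 6.14 and 6.16 in controls. That of the mitochondrial ribosome was 5.26 against 4.82, 4.67 and 4.78, with 4.69 in both controls. GM-CSF and STAT5 targets lost theirs without control library 2 (0.105, over alternatives 0.00326 to 0.204) and monocyte and macrophage markers without FAC library 7 (0.0644, over alternatives 1.11e-05 to 0.365).

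Camera called 20 of 33 lists between FAC and DFO. Higher with FAC were eosinophil genes (median 1.00, 16 of 22 higher and 2 lower, the same adjusted over the list alone, adjusted p 2.95e-15), the stress and unfolded protein response (0.68, 17 of 22, 3.29e-10), and the cell cycle (0.51, 29 of 35 higher and 2 lower, 30 and 2 adjusted over the list alone, 7.38e-09). Higher too were oxidative phosphorylation (0.52, 55 of 76, 64 adjusted over the list alone, 1.06e-06), the mitochondrial ribosome (0.42, 47 of 78, 55 adjusted over the list alone, 2.05e-06), glycolysis (0.63, 15 of 21 higher and 3 lower, 6.69e-06) and antioxidant and ferroptosis defence (0.51, 11 of 20 higher and 2 lower, 13 and 2 adjusted over the list alone, 0.000322). Also higher were ribosome biogenesis and Myc (13 of 25, 15 adjusted over the list alone, 0.0136), GM-CSF and STAT5 targets (8 of 16 higher and 3 lower, 0.0136) and heme synthesis (8 of 15 higher and 1 lower, 9 and 1 adjusted over the list alone, 0.0149). The others were the tricarboxylic acid cycle (11 of 19, 0.0159), iron-sulfur cluster assembly (16 of 28 higher and 1 lower, 18 and 1 adjusted over the list alone, 0.0256) and the hypoxia response (12 of 21 higher and 3 lower, 0.0336). Lower were dendritic cell markers (median -1.59, 11 of 12, 12 adjusted over the list alone, 7.69e-17), the interferon response (-1.58, 20 of 20, 2.57e-14), and neutrophil markers (-1.22, 13 of 15 lower and 1 higher, 5.11e-09). Lower too were megakaryocyte and platelet markers (-0.77, 8 of 10, 0.00025), progenitor markers (-0.59, 12 of 18 lower and 3 higher, 0.002), monocyte and macrophage markers (-0.45, 8 of 17 lower and 2 higher, 0.002) and NF-kB and IL-33 targets (-0.60, 15 of 25 lower and 2 higher, 16 and 2 adjusted over the list alone, 0.00303). With an estimated correlation 4 held, eosinophil genes (0.00607), dendritic cell markers (0.0123), the cell cycle (0.0301) and antioxidant and ferroptosis defence (0.0456), and the other 16 had adjusted p-values from 0.0722 to 0.573. Without FAC library 6 iron-sulfur cluster assembly (0.0923, over alternatives 0.00272 to 0.573) and the hypoxia response (0.0563, over alternatives 0.00332 to 0.323) lost the call. The median was then 0.34 for oxidative phosphorylation, 0.29 for the mitochondrial ribosome and 0.30 for antioxidant and ferroptosis defence.

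**Figure D3:**
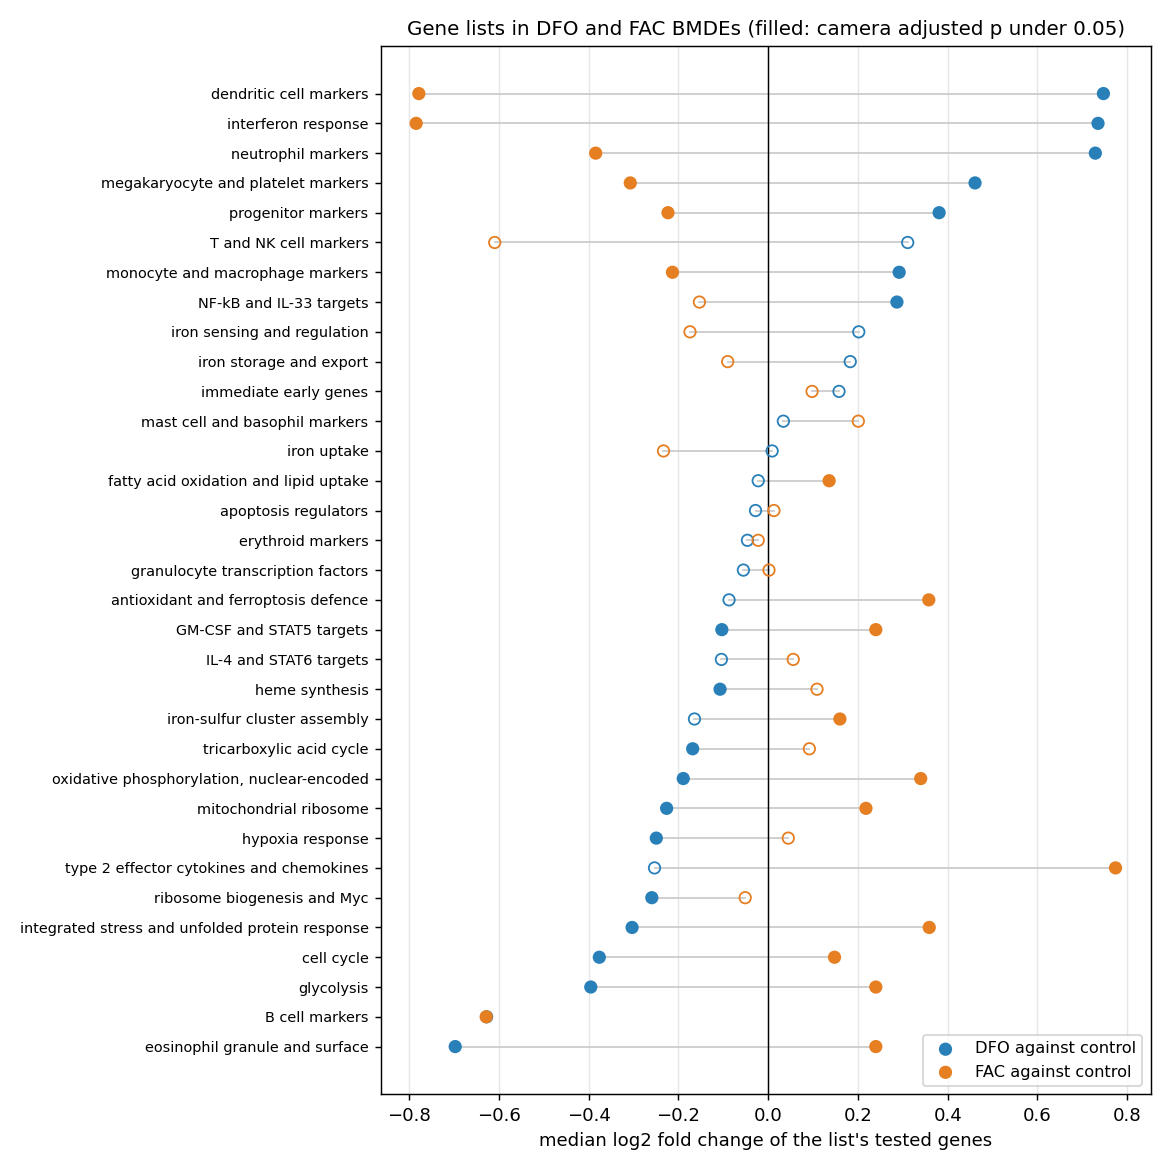
Median log2 fold change of each gene list (horizontal axis) with DFO and with FAC against control BMDEs. Filled points have a camera adjusted p under 0.05. Eosinophil genes lie at -0.70 with DFO and 0.24 with FAC, and dendritic cell markers at 0.75 and -0.78. B cell markers lie at -0.63 in both, which share the same controls. Between FAC and DFO, which is not drawn, the B cell median was -0.20, not called.

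Of the iron lists, uptake was not called with DFO (2 of 10 genes higher, adjusted p 0.444), with FAC (1 higher and 2 lower, 1 and 3 adjusted over the list alone, adjusted p 0.0528) or between them (3 higher and 5 lower, 0.128). With FAC it was called lower without control library 2 (0.0248) or FAC libraries 5 (0.0374) or 6 (0.0127), over alternatives 0.00358 to 0.208, and between FAC and DFO without FAC library 6 (0.0458, over alternatives 0.000132 to 0.269). Iron storage and export was not called either (adjusted p 0.104, 0.981 and 0.356). It had 1 of 11 genes higher with DFO (2 and 1 lower adjusted over the list alone), 1 higher and 1 lower with FAC (3 and 2 adjusted over the list alone), and 3 higher and 5 lower between them. Iron sensing and regulation was not called (0.125, 0.527 and 0.194), and heme synthesis was not called with FAC (0.0634). Other lists not called with DFO had adjusted p-values of 0.0978 for antioxidant defence, 0.0992 for iron-sulfur cluster assembly and 0.139 to 0.717 for IL-4 and STAT6 targets, immediate early genes, T and NK cell markers, type 2 effectors, fatty acid oxidation, erythroid markers, apoptosis regulators, granulocyte transcription factors and mast cell and basophil markers. With FAC they were 0.0578 for T and NK cell markers, 0.0622 for mast cell and basophil markers and 0.202 to 0.981 for the tricarboxylic acid cycle, granulocyte transcription factors, the hypoxia response, NF-kB and IL-33 targets, immediate early genes, IL-4 and STAT6 targets, apoptosis regulators, erythroid markers and ribosome biogenesis. With FAC, T and NK cell markers were called lower without control library 1 (0.0193) or FAC library 6 (0.0263), over alternatives 0.0193 to 0.416, and mast cell and basophil markers higher without control library 2 (0.00917) or FAC library 5 (0.0169), over alternatives 0.00917 to 0.583. Between FAC and DFO they were 0.069 for T and NK cell markers, 0.0775 for type 2 effectors, 0.128 for fatty acid oxidation and 0.406 to 0.806 for IL-4 and STAT6 targets, granulocyte transcription factors, mast cell and basophil markers, immediate early genes, B cell markers, apoptosis regulators and erythroid markers. Median, mean and test differed in sign for erythroid markers in all 3 comparisons, for apoptosis regulators with FAC and between FAC and DFO, and for the hypoxia response with FAC. Adjustment over the list alone changed the counts of 19 lists with DFO, 20 with FAC and 13 between them, by at most 5, 8 and 9 genes.

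The signatures ask whether DFO and FAC move BMDEs along the difference between GMPs and eosinophils. Each set held the 200 genes with the smallest p among those called and at least 2-fold higher in 1 group. Of the set higher in GMPs 196 genes were tested in BMDEs, 33 were higher and 7 lower with DFO (adjusted p 0.0174), 1 higher and 29 lower with FAC (7.4e-11), and 20 higher and 89 lower with FAC against DFO (1.03e-06). Of the set higher in bone marrow eosinophils 193 were tested, and none of the 3 comparisons was called (adjusted p 0.533, 0.333 and 0.965). Its genes went both ways, 42 higher and 34 lower with DFO, 22 and 27 with FAC, and 63 and 70 with FAC against DFO. This set comes from libraries in which markers of other cell types were also high. Of its 200 genes 9 are in the eosinophil list, 8 in the neutrophil, 7 in the erythroid and 3 in the B cell list, and eosinophil and neutrophil lists moved in opposite directions in BMDEs. The set therefore does not stand for eosinophil genes alone. With an estimated correlation 0 of the 6 tests were called, with adjusted p-values from 0.536 to 0.985. The T2 signatures were not called by camera in any of the 6 tests, with adjusted p-values from 0.132 to 0.201, and from 0.522 to 0.603 with an estimated correlation.

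The effects of DFO and FAC were opposite for most genes called in both. Of the genes called higher with DFO 342 were lower with FAC, against 34.8 for independent calls, and of those lower with DFO 130 were higher with FAC, against 11.4. Calls in the same direction were fewer, 3 higher in both against 14.3 and 12 lower in both against 27.6. These overlaps rest on the numbers called against control and moved with them. Without control library 1 there were 45 genes higher with DFO and lower with FAC (1.05 for independent calls) and 5 the other way round (0.0683), and without control library 2 there were 51 (1.29) and 9 (0.151). Without DFO libraries 11, 12 and 9 they were 164 and 50, 165 and 58, and 172 and 60. Without FAC libraries 5, 6 and 8 they were 186 and 54, 1062 and 790, and 191 and 45. With only the 2 arms in each fit they were 84 and 19, with 3 higher and 7 lower in both, and with length and GC offsets 534 and 524, with 15 and 24. Across all tested genes the 2 effects had a Pearson correlation of -0.42 and a covariance of -0.0613 (jackknife SE over libraries 0.509 and 0.0768), where simulated unchanged groups with the same shared controls gave 0.634 and 0.0307. Among genes with a mean above the median the correlation was -0.654, against 0.634 simulated. Without control libraries 1 and 2 it was -0.582 and -0.639 among those genes. Across all genes it was -0.027 without control library 1 and was 0.042 without control library 2. Without any 1 DFO or FAC library it lay between -0.445 and -0.41 across all genes. The jackknife SE therefore rests mostly on the fits with 1 control library left, and is no plain measure of the spread between libraries. With 1 control library for each arm, so that the 2 effects share none, the correlation was -0.363 (DFO against control 2, FAC against control 1) and -0.393 (the other way round), and -0.671 and -0.653 among genes with a mean above the median. These separate-control values, and those above the median without a control library, were added after the data had been seen, and genes are not independent replicates.

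**Figure D4:**
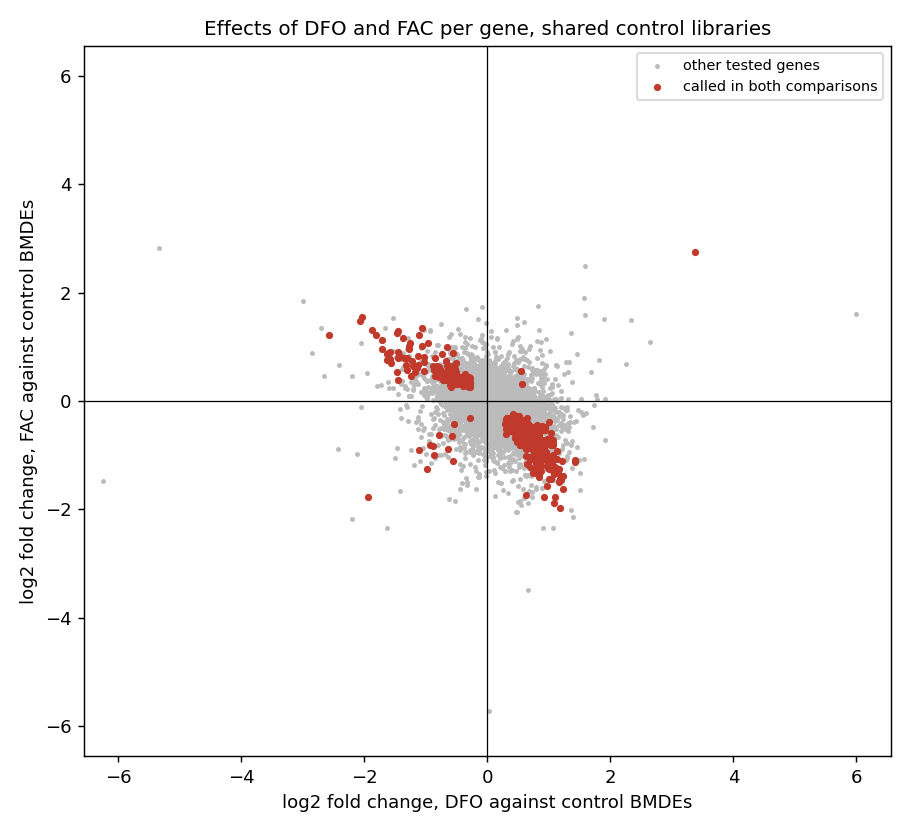
Log2 fold change with DFO (horizontal axis) and with FAC (vertical axis) against the shared control BMDEs, 1 point per tested gene; red points were called in both comparisons. Most red points lie in the quadrants of opposite sign, 342 higher with DFO and lower with FAC and 130 the other way round.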

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

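No test in this part was chosen after its result was seen, but the length and GC offsets were added after the data had been seen. Of 48 measures in the 4 FAC libraries, 6 had a library set apart by Dixon's ratio, the gap to the nearest library over the range of the 4, and chance gives about 1 in 20. FAC library 6 accounted for 4 of the 6. The ratio takes no account of size, and some of these gaps are small.

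The Tfrc level was 340.1 CPM in FAC library 7, and the next library had 316 CPM. The mean log2 CPM of B cell markers was 3.62 in FAC library 5, with the next at 3.55. In FAC library 6 it was 7.03 for antioxidant and ferroptosis defence, with the next at 6.90, 7.01 for the cell cycle, with the next at 6.97, and 5.59 for apoptosis regulators, with the next at 5.51. Transcript length and GC content accounted for 37.7% of the deviation of FAC library 6 from the mean of all BMDE libraries, and for 4.8% in the next FAC library.

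Oxidative phosphorylation genes were higher in FAC than in DFO BMDEs, 55 of 76 members. After offsets for transcript length and GC content 61 of 76 members were higher, and without FAC library 6 67 of 76 were. Higher calls among all genes rose too, from 2959 to 4261 with offsets and 4003 without that library, so the number of members is no measure of size. The list's median was 0.52, 0.35 with offsets and 0.34 without FAC library 6, where the median of all genes was -0.01, 0.08 and 0.01. The list stayed above other genes in both (adjusted p 0.000132 and 2.07e-07; 1.06e-10 to 0.558 over its alternatives). This speaks against length or GC bias, or FAC library 6, as the whole cause, although the size fell with each. The adjusted p was 0.558 with an estimated correlation, so these genes moved too closely together for the number of members to count as independent evidence. An effect of iron itself stays open and untested, as does a batch between the arms, since the labels give none. A change in the make-up of the culture stays open too, since eosinophil, neutrophil and dendritic cell markers moved in the same comparison. Cultures that hold every arm in each batch, with iron added back to DFO in 1 more arm, would separate iron from a batch. Counts of each cell type would be needed for the make-up.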

How the results depend on the processing

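The length and GC offsets, the correlation of effects among genes with a mean above the median without either control, and that with separate controls, were chosen after the data had been seen. The cause of the changes below was not tested unless given.

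For bone marrow eosinophils against GMPs, 2413 genes became 4055 with DESeq2 and 747 (without GMP library 1) to 4623 (without eosinophil library 3) when a library was left out. The 17 lists became 0 with an estimated correlation and 15 to 20 without a library. Offsets turned Mrpl14 to -0.079 (SE 0.197) and the median of oxidative phosphorylation, with an adjusted p of 0.26 (4.89e-07 to 0.794 over its alternatives). Of the 2413 genes 1758 were also called with offsets. In simulated data 2-fold changes were recovered for 1.5% of genes in this comparison, at the greatest depth of the 3 tables, so the spread between libraries limited it more than depth.

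For T2 against resting eosinophils the 8632 genes became 3122 at a 2-fold minimum and 8300 to 8520 without a library. The 14 lists became 5 with an estimated correlation and stayed 14 without any library. Fry called 29 lists, but it does not compare a list with other genes, of which 76.1% were called here.

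With DFO the 1460 genes became 2915 with offsets, 5982 with only the 2 arms in the fit, 195 at a 2-fold minimum and 217 (without control library 2) to 4899 (without FAC library 6). The fit without the FAC arm drops FAC library 6 from the shared spread. The 19 lists became 5 with an estimated correlation and 18 to 19 without a library. With FAC the 761 genes became 1678 with offsets, 116 with only the 2 arms, 1300 with DESeq2, 142 at a 2-fold minimum and 76 (without control library 1) to 2728 (without FAC library 6). The share called higher was 29.2%, and 55.2% with offsets; with DFO it was 55.8%, and 45.3% with offsets or 48.3% without FAC library 6. The 18 lists became 4 with an estimated correlation and 17 to 20 without a library. Between FAC and DFO the 6080 genes became 1262 at a 2-fold minimum and 4250 to 7855 without a library, the share higher went from 48.7% to 60.6% with offsets and 51% without FAC library 6, and the 20 lists became 4 with an estimated correlation and 19 to 20 without a library.

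The 3 signature calls from eosinophils and GMPs became 5 with 50 genes a side and 0 with an estimated correlation, and stayed 3 without any BMDE library. The 0 T2 signature calls became 3 with 500 genes a side and stayed 0 without any BMDE library. The correlation of the DFO and FAC effects ran from -0.445 (without DFO library 9) to 0.042 (without control library 2), and was -0.027 without control library 1. Among genes with a mean above the median it was -0.582 and -0.639 without control libraries 1 and 2. With 1 control library for each arm it was -0.363 and -0.393, and -0.671 and -0.653 among those genes.

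Whether equal replicate numbers pair the libraries is not known. Same-number correlations were 0.012, 0.005 and 0.119 in the GMP table and -0.009, -0.022 and 0.033 in the T2 table. Libraries with different numbers reached 0.144 and -0.176 in the GMP table. Correlations over so few libraries cannot decide the pairing. With the number as a block the counts were 1419 and 8498. No paired analysis was possible in BMDEs because the arms share no replicate numbers. Alternatives for normalized values were not run, since the tables hold counts.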

Other observations

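The tests of the marker patterns below were chosen after their results were seen, and the splits of the libraries were planned.

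Eosinophil genes moved one way and neutrophil and dendritic cell genes the other between DFO and FAC BMDEs. The eosinophil and dendritic cell lists stayed called between FAC and DFO with an estimated correlation (adjusted p 0.00607 and 0.0123, the highest over their alternatives), while the neutrophil list did not (0.134; 1.62e-16 to 0.134 over its alternatives). The control libraries enter the comparison of FAC with DFO only through the shared spread. A lower share of eosinophils alone would move markers found only in other cell types alike. The 6 lists of other cell types moved apart, with medians from -1.59 to 0.22 (permutation p 3e-04 over 70 members). The smallest p that 100000 resamples can give is 1e-05. That permutation shuffled single genes between lists, and genes are not independent, so its p may be too small. Gata2 and Flt3 are also in the progenitor list, so not every member marks other cells alone. The test therefore cannot decide whether a lower share of eosinophils is the whole cause. A change in the make-up of the culture, with more dendritic and neutrophil cells under DFO, and a change within the eosinophils both stay open, since no value separates them. An effect of iron on eosinophil differentiation stays open too. The signature higher in GMPs was higher with DFO and lower with FAC by camera at the preset correlation (adjusted p 0.0174 and 7.4e-11). With an estimated correlation neither was called (adjusted p 0.895 and 0.536). That test reads whole cultures, so it cannot separate differentiation from a change in their make-up. Counts of each cell type in the cultures, or RNA of eosinophils sorted from each arm, would separate these explanations.

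Markers of other cell types were higher in bone marrow eosinophils than in GMPs. Without library 3, 6 of 6 lists had most of their members called higher, dendritic cell markers (7 of 12, and 5 of 11 with library 3) and monocyte and macrophage markers (9 of 17, with 6 lower) by the least. Higher calls among all genes rose too in that fit, from 1585 to 2545, so the number of members is no measure of size. These 6 lists argue against eosinophil library 3 alone, although without it the monocyte and macrophage list lost its call (adjusted p 0.00526 to 0.0502; 0.000664 to 0.317 over its alternatives). RNA from other cells in the eosinophil libraries could be a source, and the tables cannot tell: 0 of 6 lists had 90% or more of their members deviating together between library 3 and libraries 1 and 2, the nearest being B cell markers with 8 of 10 and neutrophil markers with 11 of 14. Of 27 members under 1 CPM in GMPs 25 were called higher and 0 lower. Of the neutrophil markers, Ngp was at 15940 CPM and Ltf at 6059 CPM, against 9.60 and 9.25 CPM in GMPs, and how these cells were sorted is not given. Resting eosinophils held 50 of the 74 members at 1 CPM or more.

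Of the 10 splits of the 6 libraries of the GMP table, 1 gave as many genes as the real one (2413, highest other 0) and 1 as many lists (17, highest other 13). For T2 against resting eosinophils 1 of 10 gave as many genes (8632, highest other 0) and 2 as many lists (14, highest other 14). These splits are too few for a share under 0.05. Between FAC and DFO 1 of 35 splits, the real one, gave as many genes (6080) and 1 as many lists (20, highest other 19). This argues against chance for the number of genes but does not exclude it. The number of lists barely set the real split apart. The highest other split, FAC library 7 with the 3 DFO libraries, gave 4086 genes, and that with FAC library 6 gave 928. DFO and FAC against control were not split, since the control group holds fewer than 3 libraries.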
